A study of Mus musculus with 6 samples.

How the data were processed

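Olfactory mucosa was dissected from 3 control mice and 3 mice that lacked the eC element, all male and on postnatal day 30, and the design text calls them separate animals. Per the labels' protocols, total RNA was isolated with a column kit, depleted of ribosomal RNA and made into strand-specific Illumina libraries. Per the submitters' processing notes, STAR 2.6.0, DESeq2 and the genome build GRCm38.p6 were used; the program that assigned reads to genes, its annotation and its strand setting are not given in the sources used here, so reads shared by overlapping genes or close copies are uncertain. The authors deposited 1 table with 40273 genes and, per the file headers, a normalized value for each of the 6 libraries. These values, used as a signal that is never negative, are gene counts that the authors divided by a size factor per library. The deposited table also holds the authors' log2 fold change with its standard error, a test statistic that the authors derived from both (a score), and the authors' p-value and adjusted p-value. The authors' log2 fold change is coded as control over deletion, the opposite of the direction used here, and only counts of genes from these columns are reported.

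In each library, 100% of the deposited values above 0 were whole multiples of the value of 1 read (within a tolerance of 0.001 reads), so the reads could be recovered. They summed to 50906277, 31281010 and 31100948 reads in control replicates 1, 2 and 3 and to 49279931, 34169776 and 30342763 in deletion replicates 1, 2 and 3. A gene at 0 in all 3 deletion libraries was compared with a floor of 3 reads over the group, which covers counting error only. Libraries of a group were compared with a chi-square test of their reads, whose statistic per gene lay between 20.3 and 52.8, so no library was a copy of another of its group. Because the values are normalized and not raw counts, limma was used for the main test in place of edgeR's quasi-likelihood test, which had been written down for raw counts; edgeR on the recovered reads, an alternative added after the data were seen, tested 19953 genes and called 15, the same 15 genes as limma.

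The main test was limma 3.58.1 (trend option) in R 4.3.3 on log2(value + 1) with the group as the single term, over the 20368 genes with a value of at least 10 in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(value + 1) scale and understates the change of low genes. Normalized counts are given as mean ± SD and log2 fold changes with their standard error. Class I receptors were the genes with an odorant receptor symbol on chromosome 7 from 1 Mb below to 3 Mb above the element (151 genes, 118 tested), and class II receptors all others (1170 genes, 902 tested). Positions came from GENCODE vM21 on GRCm38, in which 39985 of the 40273 gene identifiers were found. The design text gives no build for the element's coordinates; they were taken as GRCm38, where they fall inside the class I cluster. For tests of the cluster as a region, its bounds were the first and last tested class I genes (102476579 to 105342270). Distances run from the element to the nearer gene end. Gene lists, fixed before the data were examined, were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, for lists with at least 5 tested genes, with adjustment over the 29 lists. Shares of reads were compared with an exact two-sided permutation test of the group means.

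Genes were named by a rule fixed at the same time as the lists. It took the 5 tested class I genes nearest to the element on each side, and the 10 largest falls and 10 largest rises among genes past the threshold whose groups did not overlap (9 and 6 were found). It also took, of each list with a member past the threshold, the 4 members with the smallest p, and always Hbb-bs, Hbb-bt, Omp, Bcl11b and Lhx2. Olfr571 was added as the gene that the element overlaps; other names were chosen after their values were seen.

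The scripts were tested on simulated counts drawn from the real genes' means, with 200 genes changed. For the deletion against control comparison, limma ran on 19612 genes and recovered 70.1% of the genes changed by a log2 of 1, 94.0% of those changed by 2 and 100% of those changed by 3, with 15 false calls. In the same simulation edgeR made 16 false calls, limma voom 14 and DESeq2 38. The changed genes were not drawn from those with the lowest means. A simulated shift of the class I list by -0.75 was fitted with a median of -0.74 and called by camera with both correlations. Of the 28 lists tested, 0 others were called. The simulated genes were drawn independently of each other and without the library sets described below. The simulation therefore does not show how camera performs on lists whose genes vary together, such as the real class I list (estimated correlation 0.79).

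The alternatives were DESeq2 1.42.0, edgeR 4.0.16 and limma voom on the recovered reads, other normalizations, other filters on low values, the replicate number as a block, leaving out each library in turn (with the same genes tested), receptor pseudogenes left out, and other distance windows. Alternatives chosen after the data were seen were pseudocounts of 0.5 and 5, robust variances, receptor classes from family names, and the library set (3 libraries with few and 3 with many genes with a read) as a term or analysed apart. The set is a property found in the data, not a batch named by the labels. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used to read the table, and matplotlib 3.10.9 for the plots.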

Results

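Total RNA was sequenced from the olfactory mucosa, the nasal tissue that holds the olfactory sensory neurons, of 6 male mice on postnatal day 30. The mice fell into 2 groups, 3 controls that carried the eC element and 3 mice that lacked it, all on the mixed background 129S6;C57BL/6J. The element is a 1005 bp stretch of chromosome 7 (102916999 to 102918004, read here as GRCm38) inside the cluster of class I odorant receptor genes, and the series title names it as an enhancer of that receptor class. Odorant receptors are G protein-coupled receptors of which a mature sensory neuron expresses a single gene. The class I genes lie together in 1 cluster on chromosome 7, and the class II genes are spread over many chromosomes. The comparison asks which receptor genes, and which other genes, differ in level when the element is gone.

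The control libraries held 50906277, 31281010 and 31100948 reads assigned to genes and the deletion libraries 49279931, 34169776 and 30342763 (replicates 1, 2 and 3). The libraries fell into 2 sets of 3 by the number of genes with a read, which the labels do not explain. Control replicate 1 and deletion replicates 1 and 2 (set A) had reads for 26564 to 27879 genes, and control replicates 2 and 3 and deletion replicate 3 (set B) for 36197 to 37456. The first principal component, with 66.1% of the variance, parted the same sets. Class I receptors differed between these sets by a median log2 of 1.14 (B over A), so values within the sets, or with the set as a term of the model, stand beside the group comparisons.

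The element overlaps the receptor gene Olfr571 (ENSMUSG00000043310.3, chromosome 7, 102905090 to 102917536, minus strand), and there it covers exon 1, a 5′ untranslated exon, of the transcripts Olfr571-202 (363 bp) and Olfr571-203 (384 bp). Olfr571 had 43.1 ± 3.12 normalized counts (SD, n = 3) in the controls, from 61, 39 and 34 reads, and no read in any of the 3 deletion libraries. Against a floor of 3 reads over the deletion group it was at least 44.2-fold lower (adjusted p = 0.00749, limma). Without control replicate 1, 2 or 3 it did not pass (adjusted p = 0.117, 0.284 and 0.185, limma), while its fitted log2 fold change of -5.46 stayed at -5.43, -5.43 and -5.52. The gene was at 0 in the deletion libraries of both sets, which checks the group labels.

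None of the 10 measured class I genes closest to the element on either side, Olfr571 aside, passed the test across all genes; 9 had a fold change below 0 and 1, Olfr568, above. Olfr568, 38.9 kb below the element, had 5.85 ± 1.87 normalized counts in the controls and 81.9 ± 46.7 in the deletion libraries (SD, n = 3), a log2 fold change of 3.50 ± 0.44 (SE; adjusted p = 0.0603, limma). Fitted with the library set as a term it was 3.84 ± 0.28 (adjusted p = 0.000405, limma; 5.76e-07 to 0.496 over its alternatives), so that model called it higher. With the group as the single term, DESeq2 (adjusted p = 5.76e-07) and limma without a filter (adjusted p = 0.0291) also called Olfr568 higher. Limma with the replicate number as a block did too (adjusted p = 0.00763). EdgeR with the group only did not (adjusted p = 0.104), nor did any of the 6 fits without 1 library. Olfr566, 58.2 kb below, had 207 ± 60.3 normalized counts in the controls and 35.8 ± 48.5 in the deletion libraries (SD, n = 3), where replicates 1 and 2 were at 8.96 and 6.62 and replicate 3, of set B, at 91.7. Its log2 fold change of -3.39 ± 0.84 did not pass (adjusted p = 0.982, limma), but did without deletion replicate 3 (adjusted p = 0.00109, limma; 0.000244, in set B alone with its 1 deletion library, to 1.00 over its alternatives). Olfr569, 26.1 kb below, had 80.8 ± 30.3 against 38.3 ± 11.3 (log2 fold change -1.02 ± 0.35). Olfr570 and Olfr561 below the element and Olfr572, Olfr575, Olfr576, Olfr577 and Olfr578 above it had log2 fold changes between -0.83 (Olfr577) and -0.37 (Olfr576), and between -0.39 (Olfr578) and 0.07 (Olfr576) with the library set as a term. Olfr572, the closest at 6.41 kb, had 61.6 ± 24.9 normalized counts in the controls and 46.5 ± 22.3 in the deletion libraries (SD, n = 3). Olfr576 and Olfr577 overlap on opposite strands, so their reads are uncertain.

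**Figure D1:**
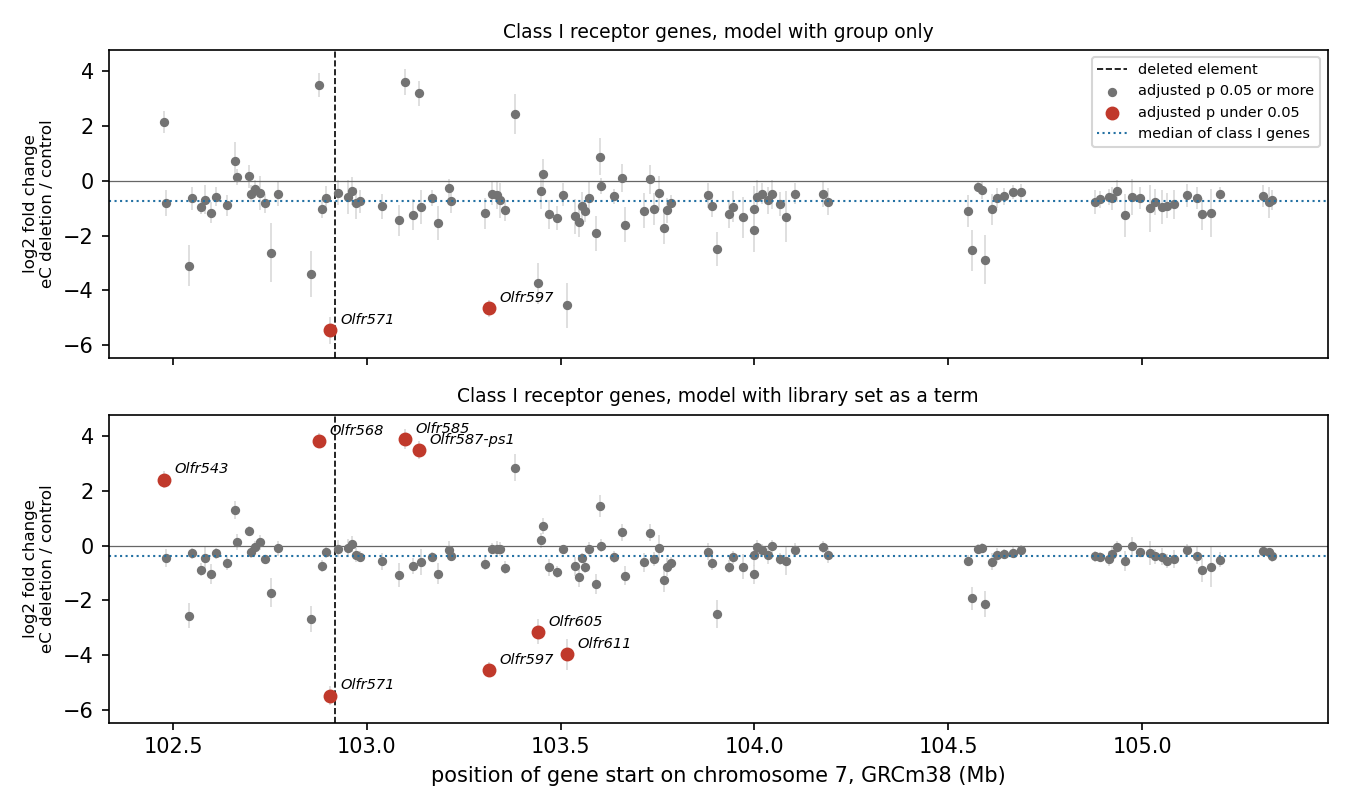
Log2 fold change (eC deletion over control, with standard error bars) of each tested class I receptor gene against its position in Mb on chromosome 7, in the model with the group only (top) and with the library set as a term (bottom). The median of the class I genes, a dotted line, lies at -0.75 in the top panel and at -0.39 in the bottom panel, and 2 and 8 genes pass the threshold.

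Across the class I cluster, 2 of the 118 measured class I genes fell and 0 rose, Olfr571 and Olfr597. Olfr597 (chromosome 7, 103316315 to 103322799), 398 kb above the element, fell from 101 ± 16.8 to 3.06 ± 0.72 normalized counts (SD, n = 3), a log2 fold change of -4.66 ± 0.31 (adjusted p = 0.00205, limma; 0.0528 without control replicate 2). Adjusted over the list alone, 12 class I genes passed, and 34 had an unadjusted p under 0.05. Below 0 were 89.8% of the class I fold changes, with a median of -0.75. Olfr585, 180 kb above the element, had 5.57 ± 1.17 and 91.8 ± 66.0 normalized counts in the controls and deletion libraries (SD, n = 3; adjusted p = 0.068, limma; 0.0426 without deletion replicate 3). With the library set as a term, a model added after the data were seen, 8 class I genes passed (24 adjusted over the list alone), 4 higher and 4 lower, and the median was -0.39. The higher genes were Olfr568, Olfr585, Olfr587-ps1 and Olfr543 and the lower ones Olfr571, Olfr597, Olfr611 and Olfr605; of these, Olfr587-ps1, Olfr543, Olfr611 and Olfr605 were named after their values were seen. Without control replicate 1, 2 or 3 the counts were 1, 0 and 1 genes, and without deletion replicate 3 there were 7.

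By distance to the element, the class I fold changes had medians of -0.69 up to 100 kb (10 genes), -0.68 from 100 to 500 kb (35 genes), -0.98 from 500 to 1000 kb (28 genes) and -0.71 beyond (45 genes). Camera with a preset correlation of 0.01 called each of the 4 bins lower (adjusted p = 2.82e-05 for the closest bin), and none with an estimated correlation (adjusted p = 0.228 for the closest bin). The closest bin includes Olfr571, the gene that the deletion cuts, as its 1 changed gene. Its test is therefore not one of neighbours alone. The medians were -0.28, -0.36, -0.61 and -0.37 with the library set as a term. For the closest bin the median was -0.61 within set A (1 control, 2 deletion libraries) and -0.05 within set B (2 control, 1 deletion library).

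Class I receptors took 8.17 ± 1.86% of all odorant receptor reads in the controls and 5.84 ± 2.32% in the deletion libraries (SD, n = 3), a difference of -2.33 percentage points that was smaller than the spread across libraries could separate (exact two-sided permutation p = 0.2; the smallest that 3 against 3 allows is 0.1). Within set A the share was 6.02% in the control and 4.51% on average in the deletion libraries, and within set B it was 9.24% on average and 8.49%. Receptor reads of both classes made up 0.355 ± 0.051% of all reads in the controls and 0.309 ± 0.061% in the deletion libraries (SD, n = 3; exact two-sided permutation p = 0.4). These were 0.297% and 0.278% within set A, and 0.384% and 0.373% within set B.

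**Figure D2:**
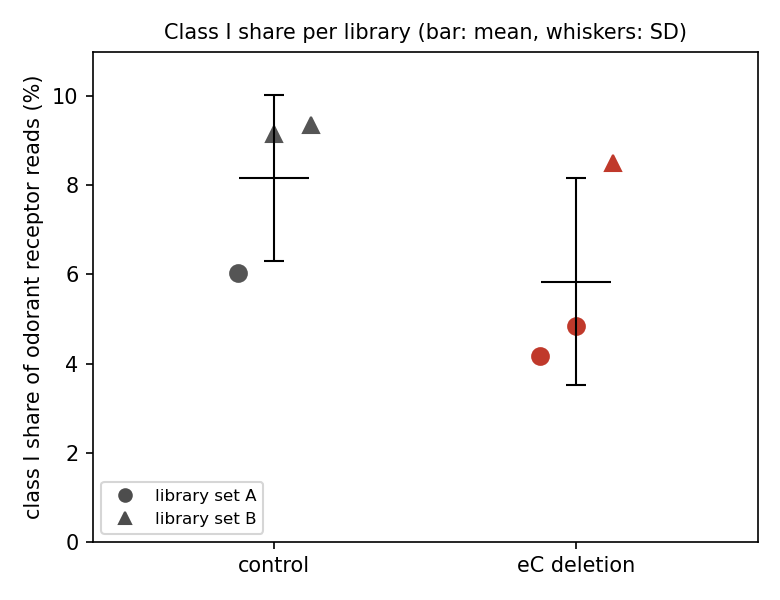
Class I share of odorant receptor reads in percent for each of the 6 libraries, by group, with circles for library set A and triangles for set B; the bar is the group mean and the whiskers the SD. The libraries of set A lie between 4.17% and 6.02% and those of set B between 8.49% and 9.34%, and in both sets the deletion libraries lie below the controls.

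Of the class II receptors, 2 of 902 measured genes fell and 0 rose; both lie on chromosome 7, 16389 and 16251 kb below the element. Olfr297 (86519968 to 86528497) fell from 244 ± 4.26 to 13.1 ± 5.18 normalized counts (SD, n = 3; log2 fold change -4.18 ± 0.27, adjusted p = 0.00205, limma). Olfr293 (86649061 to 86666045) fell from 55.4 ± 7.84 to 3.49 ± 2.20 (log2 fold change -3.74 ± 0.42, adjusted p = 0.0272, limma). Olfr297 passed without any 1 library, and Olfr293 only when the library left out was deletion replicate 3 (adjusted p between 0.0975 and 0.37 without another, limma), so each other omission left 1 class II gene. In the same group of genes, Olfr295 had 48.9 ± 8.51 and 10.1 ± 1.88 normalized counts (adjusted p = 0.0796, limma) and Olfr298 had 35.3 ± 5.72 and 134 ± 39.9 (adjusted p = 0.0679, limma) in the controls and deletion libraries. Adjusted over the list alone, 5 class II genes passed. Of the 804 class II genes on other chromosomes limma called 0, as did edgeR of those it tested, and 21 had an unadjusted p under 0.05 by limma. The median class II fold change was -0.17, and the class I median lay below it by a difference of -0.58, which was -0.34 with the library set as a term, -0.93 without deletion replicate 3 and -0.36 without deletion replicate 1. With that term 5 class II genes passed, 2 higher and 3 lower.

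Across all 20368 genes tested, 15 changed, 6 higher and 9 lower in the deletion libraries, and all 15 lie on chromosome 7, which holds 8.65% of the genes tested. On the other chromosomes limma called 0 of 18606 genes and edgeR 0 of those it tested, where 379 had an unadjusted p under 0.05 by limma. The changed genes spread over 64.1 Mb, from Hddc3 at 80343104 to Gm14372 at 144406933. Within the class I cluster lay 6 of them, and 9 lay outside it (Fisher's exact test of chromosome 7 against the other chromosomes, outside the cluster, p = 1.38e-10). In the authors' deposited table, 33 genes had an adjusted p-value under 0.05, 15 higher and 18 lower in the deletion, of which 32 lie on chromosome 7. Adding the library set as a term gave 36 genes, 35 of them on chromosome 7 and all 15 among them. DESeq2 called 40 genes, 5 of them on other chromosomes, and set B alone, with a single deletion library, gave 90, of which 41 lie elsewhere. Leaving out control replicate 1, control replicate 2, deletion replicate 2 or deletion replicate 3 gave 9, 6, 6 and 24 genes, of which 0, 1, 0 and 2 lie on other chromosomes.

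**Figure D3:**
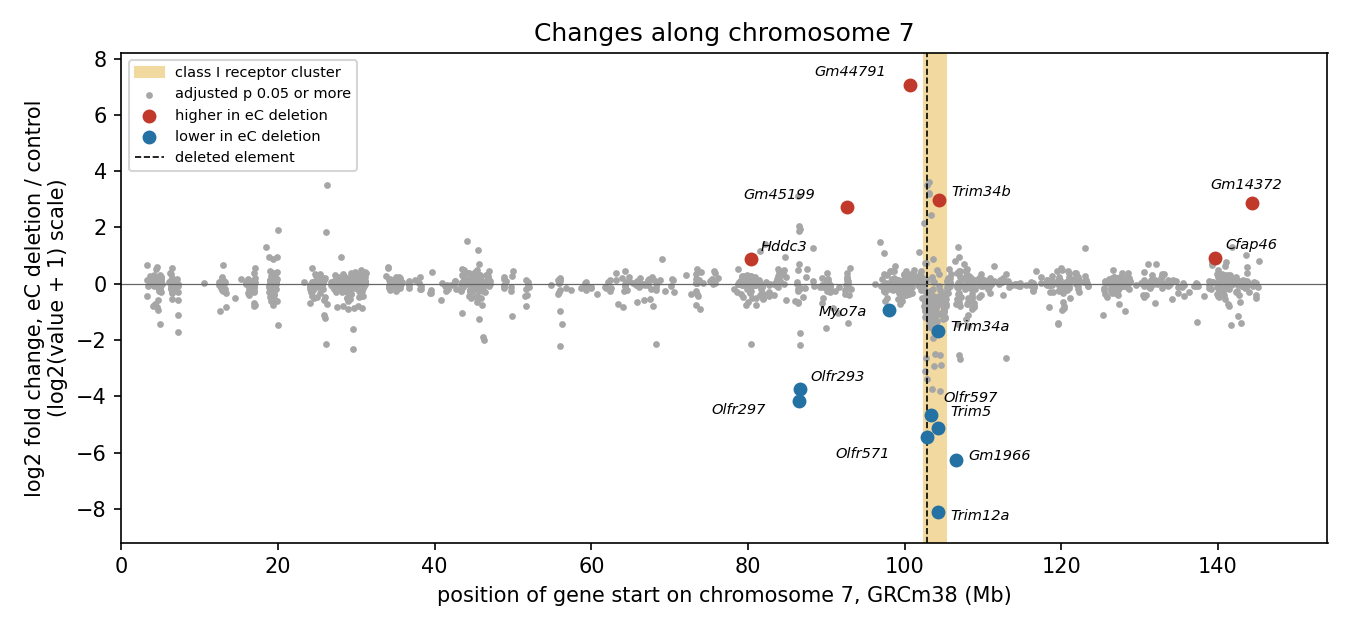
Log2 fold change (eC deletion over control, log2(value + 1) scale) of each tested gene on chromosome 7 against its start in Mb, with genes past the threshold in red (higher) and blue (lower), the class I cluster shaded and the deleted element as a dashed line. The 15 named genes lie between 80.3 and 144 Mb, 6 of them inside the cluster and 9 outside.

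Of the 16 measured non-receptor genes within the span of the class I cluster 4 changed, Trim12a, Trim5, Trim34a and Trim34b, of a family with members that restrict retroviruses. The measured cluster neighbours Trim30d, Trim30a, Trim21, Trim12c, Trim68 and Trim3 did not pass, and the family was not tested as a group. Trim12a (104299894 to 104315466) had 276 ± 1.19 normalized counts in the controls (SD, n = 3) and no read in any deletion library, at least 282-fold lower over the group (adjusted p = 3.99e-05, limma). It passed without any 1 library. Trim5 fell from 70.0 ± 2.19 to 1.02 ± 0.24 (log2 fold change -5.14 ± 0.37, adjusted p = 0.00258, limma). Trim34a fell from 304 ± 36.5 to 93.9 ± 4.64 (-1.68 ± 0.13, adjusted p = 0.00435, limma). Trim34b rose from 8.63 ± 1.62 to 73.5 ± 7.71 (2.96 ± 0.27, adjusted p = 0.00749, limma; all SD, n = 3). Without control replicate 2 or 3 Trim5 did not pass (adjusted p = 0.0792 and 0.0618, limma), nor did Trim34a without deletion replicate 2 (0.066), nor Trim34b without control replicate 2 or deletion replicate 1 or 2 (0.0641, 0.0867 and 0.159). These genes have close copies among themselves, so reads that fit several of them leave the split between them uncertain. They belong to the list of non-receptor neighbours of the class I cluster, of which 4 of 26 measured members changed (11 adjusted over the list alone), 1 higher and 3 lower. Camera called that list lower with the preset correlation (adjusted p = 9.39e-05), not with an estimated one (adjusted p = 0.646), and its median fold change was -0.09.

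**Figure D4:**
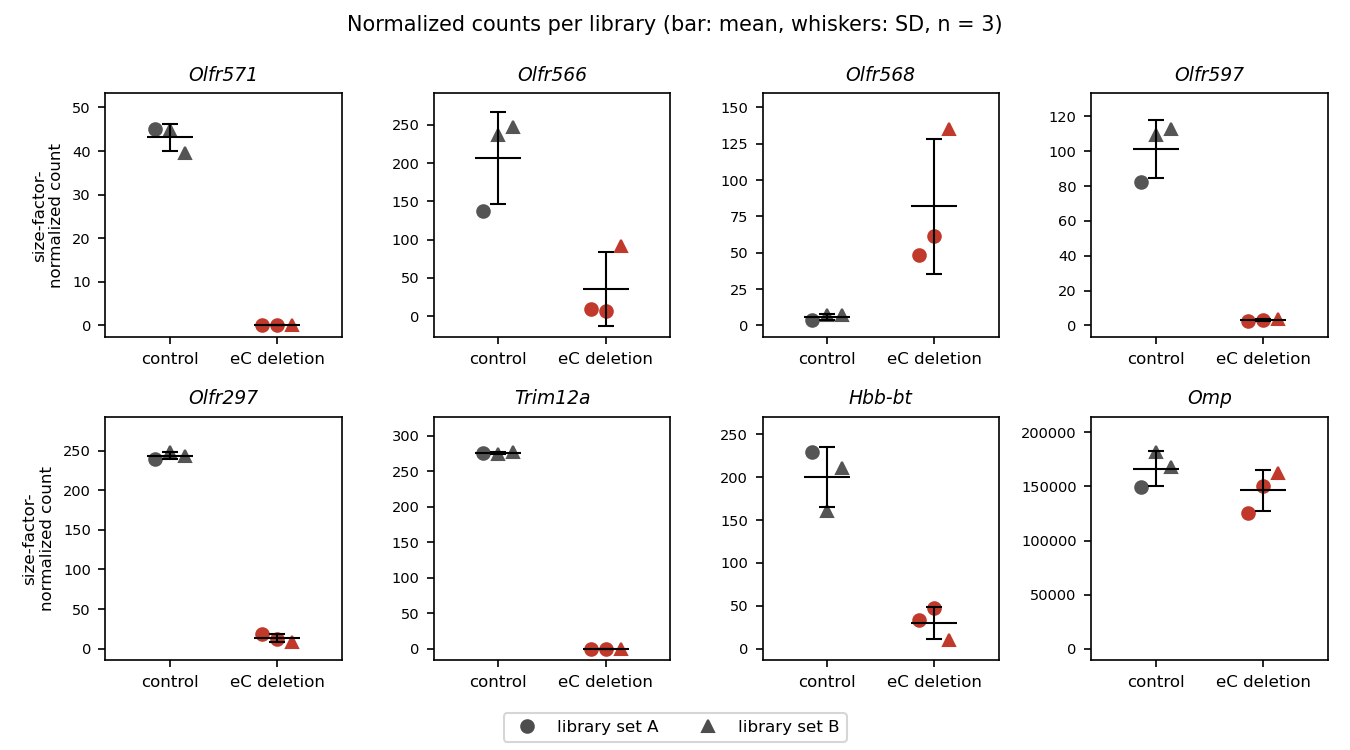
Size-factor-normalized counts of 8 genes in each of the 6 libraries, by group, with circles for library set A and triangles for set B; the bar is the mean and the whiskers the SD (n = 3). Olfr571 and Trim12a are at 0 in the 3 deletion libraries, Olfr568 lies between 48.6 and 135 there against 3.70 to 6.98 in the controls, and Omp overlaps between the groups.

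Outside the cluster, further genes of chromosome 7 differed in both directions. Gm44791, a long intergenic RNA gene at 100675088 to 100677760, rose from 2.67 ± 0.71 to 488 ± 39.6 normalized counts (SD, n = 3; log2 fold change 7.07 ± 0.23, adjusted p = 2.31e-05, limma). It shares its whole span with a second annotated gene, Gm35082, on the same strand, so its reads are uncertain. Gm14372, which lies antisense to the synaptic scaffold gene Shank2, rose from 13.9 ± 2.05 to 107 ± 14.3, and Gm45199 from 6.73 ± 1.49 to 49.2 ± 3.38 (SD, n = 3; adjusted p = 0.00435 and 0.0272, limma). Cfap46, a protein of the central apparatus of motile cilia, rose 1.89-fold, from 1161 ± 106 to 2193 ± 58.5, and Hddc3, an HD-domain hydrolase whose end overlaps Man2a2 on the opposite strand, 1.84-fold, from 838 ± 63.7 to 1542 ± 158 (SD, n = 3; adjusted p = 0.00749 and 0.0272, limma). Myo7a, the unconventional myosin of hair cell stereocilia, fell from 1130 ± 69.5 to 593 ± 43.0 (SD, n = 3; log2 fold change -0.93 ± 0.09, adjusted p = 0.00906, limma). The pseudogene Gm1966 (106596743 to 106604035) fell from 189 ± 17.5 to 2.38 ± 3.21 (SD, n = 3; -6.27 ± 0.64, adjusted p = 0.016, limma). Of these, Gm44791 passed without any 1 library. Gm14372 did not without deletion replicate 2 (adjusted p = 0.104, limma), Cfap46 without control replicate 2 (0.0792) or deletion replicate 2 (0.134), and Myo7a without control replicate 1 (0.0502), control replicate 2 (0.117) or deletion replicate 2 (0.157). Gm1966 passed only without deletion replicate 1 or 3, Hddc3 only without deletion replicate 3, and Gm45199 in none of the 6 omissions.

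The adult beta-globin genes, 895 and 909 kb above the element, did not pass in the group comparison by limma. DESeq2 with the group only called both lower (adjusted p = 1.76e-07 for Hbb-bt and 0.00122 for Hbb-bs). EdgeR with the group only called neither (adjusted p = 0.122 and 0.411). Hbb-bt had 200.1 ± 35.4 normalized counts in the controls and 29.998 ± 19.1 in the deletion libraries (SD, n = 3; log2 fold change -2.94 ± 0.50, adjusted p = 0.268, limma). Hbb-bs had 1580 ± 232 and 909 ± 184 (-0.80 ± 0.16, adjusted p = 0.442, limma). Hbb-bt passed without deletion replicate 3 (adjusted p = 0.00996, limma). With the library set as a term both passed as lower, Hbb-bt at -3.31 ± 0.34 (adjusted p = 0.00391, limma; 3.63e-10 to 1.00 over its alternatives, the lowest in set B alone with its 1 deletion library) and Hbb-bs at -0.92 ± 0.11 (adjusted p = 0.00994, limma; 7.97e-05, again in set B alone, to 1.00). The alpha-globin genes Hba-a1 and Hba-a2 on chromosome 11 had log2 fold changes of -0.43 and -0.42, and of -0.54 and -0.58 with the library set as a term, and passed in neither model (adjusted p = 0.64 and 0.612 with the set, limma). Alas2, the erythroid enzyme of haem synthesis, was at -0.49, and at -0.51 with the set (adjusted p = 1.00, limma). Hbb-bs and Hbb-bt are close copies, so the split of their reads is uncertain.

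None of 3 genes of olfactory neuron identity passed the test. Omp, the olfactory marker protein of mature sensory neurons, had 166440 ± 16035 and 146314 ± 19093 normalized counts (log2 fold change -0.19 ± 0.13), Bcl11b, a zinc finger factor with a part in the choice between receptor classes, 2820 ± 278 and 2967 ± 321 (0.07 ± 0.10), and Lhx2, a LIM-homeodomain factor of receptor gene expression, 5912 ± 165 and 6011 ± 249.5 (0.02 ± 0.06) in the controls and the deletion libraries (SD, n = 3; adjusted p = 0.982 each, limma). The 21 measured regulators of receptor gene choice had a median fold change of 0.03, and none was among the 15 genes that changed by limma and by edgeR.

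Of the 29 gene lists, camera with the preset correlation called 10, and with an estimated correlation 0 (smallest adjusted p = 0.646). The called lists with lower genes were the class I receptors (median -0.75, adjusted p = 2.13e-25; 0.819 with an estimated correlation), the class II receptors (-0.17), the trace amine-associated receptors (-0.46), which are a second family of olfactory receptors, mature olfactory sensory neurons (-0.07), the alpha-globin and haem enzyme list (-0.20), skeletal muscle (-0.58) and the cluster neighbours. Horizontal basal cells (0.31), respiratory ciliated and secretory cells (0.19) and the unfolded protein response (0.06) were the called lists with higher genes. The single genes past the threshold in these lists were class I and class II receptors and cluster neighbours. Without control replicate 2 camera called 4 lists, and without deletion replicate 1 it called 6. Several of these lists differed between the library sets as well: the trace amine-associated receptors by a median log2 of 1.04, horizontal basal cells by -0.54, skeletal muscle by 0.55 and class II receptors by 0.35 (B over A). Camera called these differences with the preset correlation, and none with an estimated one (adjusted p between 0.498 and 0.631). The sets were defined from these same libraries, so tests between them are not independent of that choice. With the library set as a term camera called 3 lists, the class I receptors, the cluster neighbours and the respiratory cells (median 0.15), and 0 with an estimated correlation. The medians of the alpha-globin list (0.18) and skeletal muscle (0.18) then lay above 0 while their tests pointed down.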

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

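The alternatives with the library set, edgeR with TMM, other pseudocounts, robust variances, receptor family names and, for the genes near the element, an estimated correlation were chosen after the data were seen, as was keeping the 20368 genes in the fits without 1 library, after a first run in which the filter removed genes at 0 in a group. The 15 changed genes were called again by DESeq2, by edgeR with 3 scalings, without a filter, with other pseudocounts, with the replicate block and with the library set as a term; edgeR with library size only and limma voom called 14 (not Hddc3). For the 33 genes of the naming rule (Olfr571 included), 655 values stayed on their side of the threshold, 42 passed it in addition and 51 no longer passed it. A sign other than the reported one came in 11 values of 7 genes that did not pass (Olfr561, Olfr570, Olfr572, Olfr575, Olfr576, Bcl11b and Lhx2), and in 0 values past the threshold. Other genes named in the text were not followed through the alternatives.

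The number of changed genes (15) was 40 with DESeq2, 46 with the replicate number as a block (47 with edgeR), 36 with the library set as a term (38 with edgeR), 2 in set A alone, 90 in set B alone and 6 to 24 without 1 library (9, 6 and 6 without control replicate 1, control replicate 2 and deletion replicate 2, and 24 without deletion replicate 3). Outside chromosome 7 lay 10 of the 46 (12 of the 47 with edgeR), 5 of DESeq2's 40, 1 of the 36 (2 of the 38) and 41 of the 90, and 1, 1 and 2 of the genes without control replicate 2, control replicate 3 and deletion replicate 3. A set alone leaves 1 sample in an arm, which is assumed to vary like the others. The labels do not say that the replicate numbers pair the samples. Correlations of the 3 numbered pairs were 0.65, -0.34 and 0.66. The pairs of replicates 1 and 3 each lie within 1 library set and the pair of replicate 2 does not. These values therefore cannot show whether the numbers pair animals. For class I receptor genes (2) the count was 8 with DESeq2, 4 without a filter, 1 at a mean of at least 50, 7 with the block (7 with edgeR), 8 with the set term (8 with edgeR), 0 in set A, 11 in set B and 0 to 7 without 1 library (0 without control replicate 2, 1 without control replicate 1 or 3, 7 without deletion replicate 3). For class II (2) it was 5 with DESeq2, 1 at a mean of at least 50, 5 with the block (5 with edgeR), 5 with the set term (5 with edgeR), 0 in set A, 7 in set B and 1 to 3 without 1 library (3 without deletion replicate 3, 1 without any other). Set A alone and the higher filter test fewer samples or genes. For the other moves the cause was not tested.

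For the class I genes within 100 kb of the element, Olfr571 included, the median of -0.69 kept its direction throughout. It kept its call in all alternatives but the estimated correlation (-0.69, adjusted p = 0.228, camera). Of the lists (10 called), an estimated correlation called 0, fry 1, the set term 3, and fits without 1 library 4 to 13 (4 without control replicate 2, 6 without deletion replicate 1). The class I list (median -0.75) was not called with an estimated correlation (-0.75) or by fry (-0.75), nor were the cluster neighbours with an estimated one (-0.090). The class II list (median -0.17) was also not called with the set term (-0.048) or without deletion replicate 1 (-0.029; -0.28 to -0.029 without 1 library). The trace amine-associated receptors (-0.46) were not called with the set term (-0.18) or without control replicate 2 (-0.29), control replicate 3 (-0.29) or deletion replicate 1 (-0.18; -0.83 to -0.18 without 1 library). Neither list was called with an estimated correlation or by fry. Not called by either were the alpha-globin list (-0.20 and -0.20; with the set term 0.18; without 1 library -0.58 to -0.043), horizontal basal cells (0.31 and 0.31; set term 0.12; 0.054 to 0.46), mature neurons (-0.073 and -0.073; no filter -0.073; set term -0.020; -0.15 to 0.0054, with the test turned to higher without control replicate 2, at -0.00937, and without deletion replicate 1, at -0.0100), respiratory cells (0.19 and 0.19; 0.14 to 0.34), skeletal muscle (-0.58 and -0.58; block -0.58; set term 0.18; -1.08 to -0.17) and the unfolded protein response (0.064 and 0.064; block 0.064; set term 0.034; -0.00293 to 0.11). Called in addition were microvillous cells without a filter (0.11), vascular cells with the block (0.095), without a filter (0.095) and without 1 library (-0.069 to 0.17), ventral zone genes without a filter (0.085) and without 1 library (-0.033 to 0.16), and, without 1 library, bone and cartilage cells (-0.10 to 0.052), lymphoid cells (-0.45 to 0.14), progenitors (-0.034 to 0.18) and choice regulators (0.0087 to 0.051). The cause was not tested.

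The shares of receptor reads kept their direction in every alternative run. Receptor families in place of the coordinate window were run by 1 family naming only, since the newer symbols were not at hand, and DESeq2 gave no value for the gene lists. Some receptors rest on few reads. The controls' 43.1 normalized counts for Olfr571 come from 34 to 61 reads, and 118 of the 151 class I genes passed the filter. Whether more depth would change this was not tested.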

Other observations

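The tests in this part were chosen after the result was seen, except the test of X-linked against autosomal reads, which was written down before.

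Independent of the deletion, the 3 libraries of set B (control replicates 2 and 3, deletion replicate 3) differed from the 3 of set A, with the group as a term of the limma model: 1080 genes were higher and 951 lower. Among the higher ones were predicted genes such as Gm10800 (164, 66185 and 136159 normalized counts in the controls, 328, 354 and 173273 in the deletion libraries; log2 B over A 9.08, adjusted p = 1.51e-07), Gm21738 (8.80), Gm10801 (8.36), Gm10718 (8.19) and Gm26870 (7.03), and also Otog (5.11), Apob (4.93) and Ttn (2.66), all named after their values were seen. Class I receptors were higher by a median log2 of 1.14 (74 of 118 genes past the threshold), trace amine-associated receptors by 1.04 (9 of 12) and class II receptors by 0.35 (189 of 902). Progenitor and cycling cell genes were lower (-0.36, 7 of 15 genes), horizontal basal cell genes too (-0.54, 2 of 7). Camera called these lists with the preset correlation (adjusted p = 2.48e-38 for class I), and none with an estimated one (adjusted p = 0.498 for class I). Pcdh10, a protocadherin, had 2451, 842 and 655 normalized counts in the controls and 6200, 5032 and 1016 in the deletion libraries (log2 B over A -2.09, adjusted p = 3.00e-04, limma). Nqo1, a quinone oxidoreductase that marks dorsal olfactory epithelium, was higher in set B (0.69, adjusted p = 0.0122, limma). The sets were defined by the number of genes with a read in these same libraries. Genes without reads in set A are thus favoured as higher in set B, and the p-values between the sets are not independent of that choice.

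A group of class II genes far from the element differed in both directions. With the library set as a term, Olfr297, Olfr293 and Olfr295 were lower (-4.30, -3.52 and -2.15) and Olfr298 and Olfr304 higher (2.02 and 3.19), all within chromosome 7, 86385657 to 86666045. Olfr304, named after its values were seen, had 5.204 ± 2.92 normalized counts in the controls and 49.7 ± 15.0 in the deletion libraries (SD, n = 3; adjusted p = 0.125, limma, and 0.0253 with the set as a term).

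Changed genes along chromosome 7: outside the class I cluster 9 genes passed the threshold there and 0 of 18606 on other chromosomes, where 379 had an unadjusted p under 0.05 by limma, edgeR called 0 and DESeq2 called 5 (41 of 90 in set B alone lay elsewhere, and 1, 1 and 2 genes without control replicate 2, control replicate 3 and deletion replicate 3). These 9 genes argue against an effect limited to the cluster as the sole source of the changes along chromosome 7. They do not show how far the element itself acts, since a linked stretch could hold them. The enrichment (Fisher's exact test, p = 1.38e-10), with 5 genes higher and 4 lower, restates the pattern, so a stretch of chromosome 7 from another strain background carried along with the deletion stays open, as does an effect of the element on distant genes of the chromosome. The background is mixed (129S6;C57BL/6J), but the strain of the targeted chromosome, and whether the animals were littermates or homozygous, are not given in the sources used here. Inside the cluster 4 of 16 non-receptor genes passed, and 8 with the library set as a term. For the genes there, a stretch from another strain and the deletion cannot be told apart, since both would be carried by the same animals.

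Class I receptors lower in the deletion libraries: the class I median lay below the class II median by a difference of -0.58, and -0.34 with the library set as a term (jackknife SE 0.25), so uneven numbers of the 2 library sets in the groups stay open. Less dorsal epithelium in the deletion samples has no support from the dorsal zone list, whose median was -0.019, and -0.029 in that model (SD of its 7 members 0.086). The trace amine-associated receptors were lower, with a median of -0.46, and of -0.18 in that model (jackknife SE 0.23). Less dorsal epithelium stays open, since the class I median differed from the dorsal zone list by -0.36 (jackknife SE 0.35) and from the trace amine-associated receptors by -0.21 (jackknife SE 0.30). Loss of the deleted element acting by distance stays open, with genes within 100 kb higher than those over 1000 kb away by 0.087 (jackknife SE 0.12). These 3 explanations cannot be told apart with 3 libraries a group, nor from a linked stretch of chromosome 7 or from variation between libraries. The fall itself is uncertain. The class I median with the library set as a term was -0.39 (jackknife SE 0.35), and camera with an estimated correlation did not call the list (adjusted p = 0.819 in the group comparison).

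The 2 library sets: in set B, 1442 autosomal genes without a read in set A had 2.05 reads per kb of exon and 160 X-linked ones 1.47, a ratio of 0.718 (95% bootstrap interval 0.617 to 0.837, 2000 draws); genomic DNA of male animals would give a ratio near 0.5. The interval lies above that value and spans the bound of 0.75 set beforehand, so genomic DNA in set B may explain part of the reads of silent genes, and stays open. It is argued against as the source of the class I rise, of which the background of silent genes makes up 14.1% (11.5 to 17.0). For more dorsal epithelium in set B the values were mixed. The class I rise lay above the dorsal zone list by 1.22 (jackknife SE 0.50, list median -0.072, SD of its 7 members 0.34). Of that list Nqo1 (0.69), Acsm4 (0.29) and Robo2 (0.15) were higher and Nrp1, Kcnq1, Cd55 and Rgmb lower. The trace amine-associated receptors rose by a median of 1.04. The list did not rise as a set, but its members differ in direction, so more dorsal epithelium stays open as the whole cause or a part. The labels name no batch and no group that follows the sets, so no biological explanation from the design was tested.

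The splits of the 6 libraries into 3 and 3, the real one included, were too few (10) for a share under 0.05. Counting the real one, as large a result came in 2 of the 10 for the number of changed genes (15, highest other 3140), class I genes (2, highest other 84), class II genes (2, highest other 265) and the difference between the classes (0.58 in size, highest other 0.91), in 4 for the class I genes near the element (0.69 in size, highest other 1.27) and in 4 for the gene lists (10, highest other 14). The split that follows the library sets gave each of these highest values but that of the lists, where it called 10. Its 3140 genes point to a structure of the samples, and with the set as a term the comparison gave 36 genes. The 8 further splits called 0 genes by limma.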
